A study of Mus musculus with 16 samples.

How the data were processed

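RNA from whole hearts of 12 week old mice was compared on 16 two-colour Agilent arrays of the 4x44K mouse design, 1 heart sample per array. The 4 genotypes were wild type, null for both MuRF1 and MuRF2 (double null), MuRF1 null with 1 functional MuRF2 allele (MuRF1 null MuRF2 het), and MuRF2 null with 1 functional MuRF1 allele (MuRF1 het MuRF2 null), with 4 arrays each. Per the labels, 50 ng of total RNA was amplified and labelled, and by their channel entries heart RNA was in the Cy5 channel and a common reference, RNA pooled from whole C57BL/6 pups of postnatal day 1, was in the Cy3 channel. The labelling protocol names only Cy3-CTP, also for the hearts, and the channel entries were followed. In wild type arrays the ratio of Cy5 to Cy3 was 3.97 (log2) for the heart myosin Myh6, -6.30 for Afp, a gene of fetal liver, and 2.63 for Trim63, whose ratio was lower in both groups without MuRF1. No array had the dyes swapped. The labels call the replicates biological, and no sample was left out.

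Per the file headers, the arrays were scanned on a GenePix scanner and read with Agilent Feature Extraction, version 9.1.3.1 for 12 arrays and version 9.5.3.1 for the 4 MuRF1 het MuRF2 null arrays. The deposited array files give the mean intensity of each spot and the median intensity of its local background in both colours. They also give a log10 ratio of Cy5 over Cy3 that the authors obtained in Feature Extraction by spatial detrending, background correction and LOWESS dye normalisation, and flags for signal over background, saturation and irregular spots. The deposited series matrix holds log2 ratios of Cy5 over Cy3; its values equal the Feature Extraction log ratio on a log2 scale minus the median of each probe over the 16 arrays. How that step was made is not given in the sources used here, and its direction was found from the values.

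The spot intensities were processed anew in R 4.3.3 with limma 3.58.1 and the package data.table, version 1.17.8. Background was corrected by the normexp method with an offset of 50, and each array was normalised by loess, with control spots and spots marked as irregular given no weight. Spots of the same probe were averaged, which left 41174 probes from 43379 spots after 1639 control spots were set aside. A probe was kept if its Cy5 signal was well above background on at least 4 of the 16 arrays, which 16810 probes met. Each gene was represented by its probe with the highest mean log2 Cy5 intensity, which gave 12331 genes. Current symbols came from the RefSeq table of the GRCm38.p6 mouse assembly by accession for 22951 probes, by symbol for 6659 and by synonym for 3109, and 8455 probes kept the name in the file. The coordinates of that table were used only to find genes near Trim63 and Trim55. The build behind the array design is not given in the sources used here.

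A value of 1 on the log2 ratio scale means that heart RNA gave 2 times the signal of the reference. The depth of an array is given as the number of probes whose Cy5 signal was well above background. The number of arrays, 4 per group, limits the precision.

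The 6 comparisons among the 4 groups were fitted with limma over all 16 arrays, with 1 mean per group and moderated standard errors. Adjusted p values follow Benjamini and Hochberg over all genes tested in a comparison, tests were two-sided, and a gene is said to have risen or fallen where the adjusted p was under 0.05. Before the data were examined, 28 gene lists were fixed for cell types, heart muscle, metabolism and stress, and for E2F targets because the series names E2F1. Lists with at least 3 measured members were tested with camera at its preset correlation of 0.01, with adjusted p over the lists of a comparison. Medians of lists are over all measured members, and those under an alternative over the members with a value on every array. They were also tested with an estimated correlation and with fry. Genes near Trim63 or Trim55 were compared with the other genes by Fisher's exact test.

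The genes named were chosen by a rule written before the data were examined. Trim63 (MuRF1), Trim55 (MuRF2) and Trim54 (MuRF3) were always taken. Against wild type, the 10 largest rises and the 10 largest falls were taken among genes that passed and whose 4 arrays in 1 group all lay above or below the 4 of the other, and the 5 largest each in the other 3 comparisons. Clone names, accessions, predicted genes and pseudogenes were skipped. Up to 4 members with the smallest p were taken from each list that passed or held a gene that passed, and the text names the first 2 of them that passed. In the 5 comparisons other than double null against wild type this was narrowed, after the values were seen, to lists that passed. Nppa, Nppb, Myh7, Myh6, Acta1, E2f1, Cdkn1a and E2F targets were taken in double null against wild type whether or not they passed. Some genes that meet the rule are not reported here. Genes named outside the rule are said to have been chosen after their values were seen. So were Myh7, Nppa, Nppb and Myh6 in MuRF1 null MuRF2 het against wild type, and Myh7 in double null against MuRF1 null MuRF2 het.

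The fit was tested on simulated data in which 50 genes each were shifted by a log2 difference of 0.5, 1, 2 or 3 between 4 double null and 4 wild type arrays. It recovered 64%, 96%, 96% and 100% of them, and 19 of 12131 unshifted genes were called. The simulated noise was independent between genes, with the same spread in every group and no difference in brightness. These numbers therefore do not show how often genes are called wrongly on the real arrays.

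Each count and named gene was recomputed with no background subtraction, with the Feature Extraction log ratio, with the series matrix values, with median centring in place of loess, with scaling between arrays, with the Cy5 channel alone, with no filter, with a strict filter, with every probe on its own, with only the arrays of the 2 groups compared, with the replicate number or the slide as a block, with array weights, with an intensity trend, and without each array in turn. The lists were recomputed with these except every probe on its own, only the 2 groups, a random slide block, array weights and an intensity trend. Overlaps were recomputed only with split wild type arrays, and the odds ratios near Trim63 and Trim55 only with windows of 5 and 20 Mb. After the data were examined, 3 more were added for counts, genes and lists: a fit without the 2 dimmest arrays, a normexp offset of 0, and Cy5 brightness as a covariate. The lists without each array in turn were also added then. Median centring moved the median of all genes by -0.49 in double null and by -0.51 in MuRF1 null MuRF2 het against wild type, and by -0.34 in MuRF1 het MuRF2 null. It moved it by -0.15 in double null and by -0.16 in MuRF1 null MuRF2 het against MuRF1 het MuRF2 null. The Feature Extraction log ratio moved it by -0.18, -0.13, -0.19 and -0.15 in double null and in MuRF1 null MuRF2 het, first against wild type and then against MuRF1 het MuRF2 null. Where a direction turns under such a scaling, its value is given beside the result or in the closing section.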

Results

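Expression was measured in hearts of 4 wild type, 4 double null, 4 MuRF1 null MuRF2 het and 4 MuRF1 het MuRF2 null mice. MuRF1, MuRF2 and MuRF3 are muscle ring finger proteins encoded by Trim63, Trim55 and Trim54, and MuRF1 is a muscle ubiquitin ligase. Each value is a log2 ratio of heart RNA to the common reference, n = 4 arrays per group. Errors of differences are standard errors from limma, and errors of group means are standard deviations.

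Cy5 signal was well above background for 15922 probes (SD 717) in wild type and 16664 (SD 524) in MuRF1 het MuRF2 null hearts. It was so for 11507 (SD 3706) in MuRF1 null MuRF2 het and 11074 (SD 3583) in double null hearts. The dimmest arrays were double null 2, with 6028 probes, and MuRF1 null MuRF2 het 1, with 6397. The Cy3 reference was well above background for 21996 to 25190 probes. By the file headers, slides 1 and 3 each held 2 wild type and 2 double null arrays. Slide 2 held the MuRF1 null MuRF2 het arrays alone and slide 4 the MuRF1 het MuRF2 null arrays alone, so slide and genotype cannot be told apart for these groups.

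**Figure D1:**
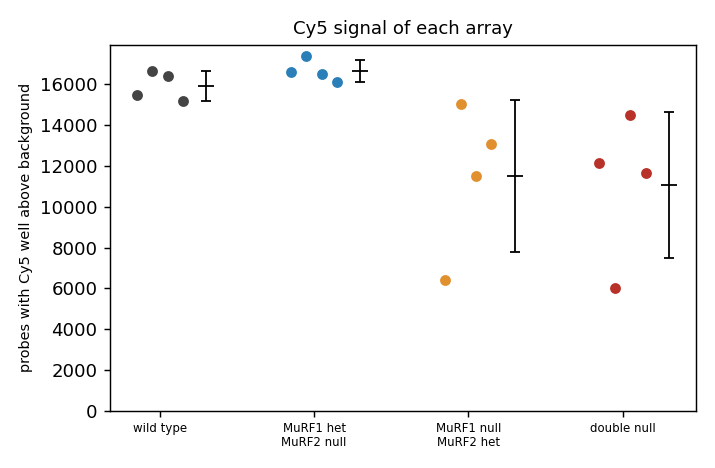
Number of probes with Cy5 signal well above background on each array (points), with the mean and SD of each group (bars), n = 4. The double null arrays ranged from 6028 to 14481 and the wild type arrays from 15165 to 16662.

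The targeted MuRF1 gene itself was examined first. Trim63 was at 2.63 ± 0.09 (SD, n = 4) in wild type hearts, at 1.94 ± 0.21 with 1 functional MuRF1 allele. It was at -0.64 ± 0.22 in MuRF1 null MuRF2 het and at -0.72 ± 0.27 in double null hearts, well above background on 2 of 4 arrays in each. Against wild type, Trim63 fell by 3.36 ± 0.14 in double null hearts (10.2-fold, adjusted p = 8.13e-10). It fell by 3.27 ± 0.14 in MuRF1 null MuRF2 het hearts (9.65-fold, adjusted p = 1.21e-09). In MuRF1 het MuRF2 null hearts it fell by 0.69 ± 0.14 (1.62-fold, adjusted p = 0.0181), with an adjusted p of up to 0.0669 when single arrays were left out. The 2 groups without MuRF1 differed in Trim63 by -0.09 ± 0.14 (adjusted p = 0.943), and this difference was 0.01 without MuRF1 null MuRF2 het 1 and 0.02 without double null 3. A dimmer Trim63 probe, above background on 3 wild type arrays and on no array of either group without MuRF1, was at 0.22 in wild type and at -0.12 in double null hearts.

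Trim55, the MuRF2 gene, passed in none of the 6 comparisons of ratios. It was at -1.73 ± 0.16 in wild type, -1.35 ± 0.56 in double null, -1.03 ± 0.48 in MuRF1 null MuRF2 het and -1.28 ± 0.19 in MuRF1 het MuRF2 null hearts. Its difference of 0.37 ± 0.25 between double null and wild type (adjusted p = 0.276) was 0.09 without double null 2, and -0.76 with median centring. The part of the gene that was removed is not given in the sources used here, so the probe is no check of the MuRF2 genotype. Trim54, the MuRF3 gene, rose by 0.61 ± 0.11 in double null hearts against wild type (1.53-fold, adjusted p = 0.00227) but was at -0.69 with median centring. That setting moved the median of all genes by -0.49. In MuRF1 null MuRF2 het and MuRF1 het MuRF2 null hearts Trim54 did not pass against wild type (0.41 and 0.11, adjusted p = 0.0829 and 0.72; under 0 with median centring).

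**Figure D2:**
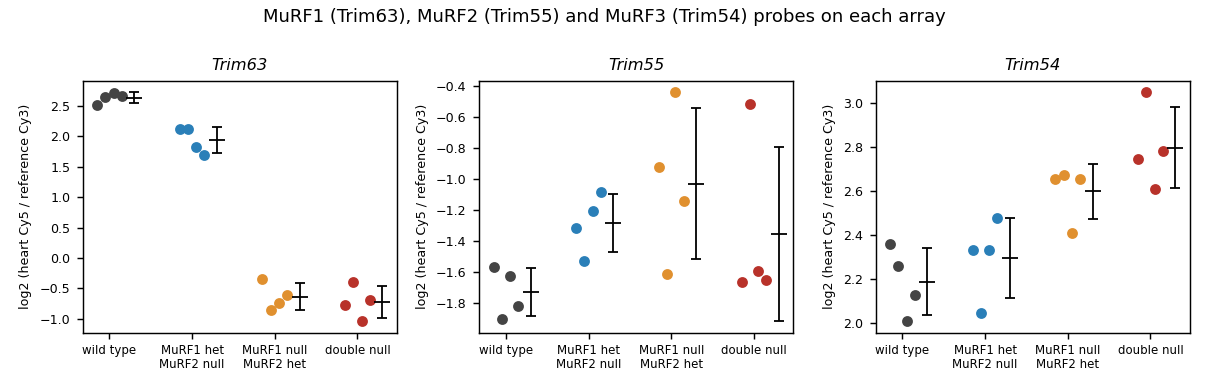
Log2 ratio of heart to reference for Trim63, Trim55 and Trim54 on each array (points), with the mean and SD of each group (bars), n = 4. Trim63 lay near -0.72 in double null and near 2.63 in wild type hearts.

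The comparison of double null with wild type hearts asks what the loss of both proteins changes. Several genes known from the fetal and stressed heart rose in double null hearts. Myh7, the slow myosin heavy chain, rose 21.6-fold (log2 4.43 ± 0.72, adjusted p = 0.000906; 5.35 without double null 1), and the natriuretic peptides Nppa and Nppb rose at least 7.47-fold (2.90 ± 0.36, adjusted p = 0.000187) and 3.35-fold (1.74 ± 0.33, adjusted p = 0.00267). Skeletal actin Acta1 rose 4.79-fold (2.26 ± 0.28, adjusted p = 0.000163) and Ccn2, a matricellular growth factor, 5.22-fold (2.38 ± 0.39, adjusted p = 0.000886). The adult myosin heavy chain Myh6 fell by 1.52 ± 0.31 (2.86-fold, adjusted p = 0.00358).

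The other largest rises were of Nmrk2, a nicotinamide riboside kinase (6.65-fold, log2 2.73, or 3.33 without double null 2), Lman1l, the secreted stress factor Gdf15 (3.85-fold), the retinol binding protein Rbp7, the LIM protein Fhl1 (3.59-fold) and Dct. After Trim63, the largest falls were of Abhd1 (4.45-fold), Slc41a3, the fast myosin heavy chain Myh4, the cytokine signalling inhibitor Cish (3.45-fold), the urocortin receptor Crhr2, the fast muscle calcium pump Atp2a1, Fndc5, the irisin precursor (3.12-fold, adjusted p = 6.52e-06), Pla2g5 and Asb15. Their adjusted p ranged up to 0.0149, and the 4 double null arrays lay all above or all below the 4 wild type arrays for each. Double null 1 had the lowest Myh7 of its group, at -0.38 against 2.81, 3.82 and 3.20 on double null 2, 3 and 4. Nppa was saturated in Cy5 on double null 3, so its folds in double null hearts are lower bounds. Fndc5 and Pla2g5 lie within 10 Mb of Trim63, and Nppa, Nppb and Rbp7 lie more than 10 and less than 20 Mb from it.

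**Figure D3:**
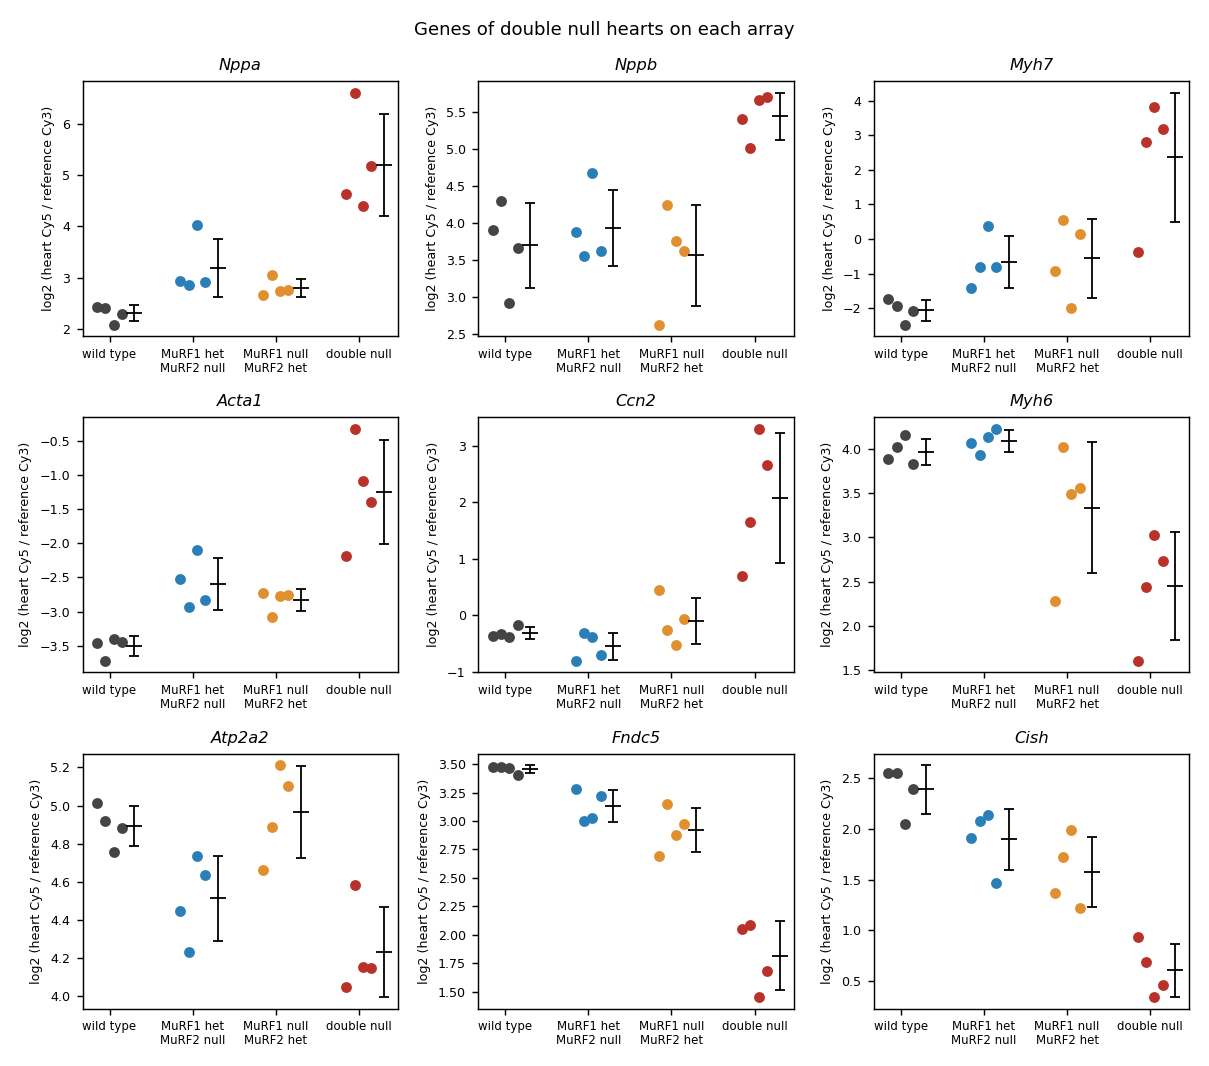
Log2 ratio of heart to reference for 9 genes on each array (points), with the mean and SD of each group (bars), n = 4. Nppa, Nppb, Myh7, Acta1 and Ccn2 were higher, and Myh6, Atp2a2, Fndc5 and Cish lower, in all 4 double null than in all 4 wild type arrays.

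Of 19 measured genes of the fetal and hypertrophic list, 8 rose and 4 fell (11 and 5 adjusted over the list alone). The 4 that fell were Myh6, the calcium pump Atp2a2, the transcription factor Nfatc1 and the actin-binding Xirp1, the last 3 chosen after their values were seen. The list's median was 0.57 (camera adjusted p = 0.0135, adjusted p = 0.502 with an estimated correlation), 0.30 on slide 1 and 0.70 on slide 3. It was -0.21 with median centring, where the median of all genes moved by -0.49. Of 6 atrial markers 3 rose, over all genes and adjusted over the list alone, namely Nppa and the myosin light chains Myl4 and Myl7, Myl7 chosen after its value was seen. The atrial median was 0.76 (camera adjusted p = 0.0135, adjusted p = 0.603 with an estimated correlation). It was 1.00 on slide 1 and 0.44 on slide 3, -0.30 with median centring and -0.03 with Cy5 brightness as a covariate. Myl4 (0.74 ± 0.21) had an adjusted p of up to 0.0663, without double null 2 or wild type 3. Sarcomere genes went both ways, with 4 rises and 5 falls among 24, over all genes and adjusted over the list alone (camera adjusted p = 0.916). Cryab, a small heat shock protein gene (0.75 ± 0.09), and Myot (1.79 ± 0.30) were among the rises.

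In the fatty acid oxidation list 14 of 29 genes fell and none rose (17 and 1 adjusted over the list alone). The nuclear receptor gene Ppara fell by 0.60 ± 0.08 and the carnitine palmitoyltransferase gene Cpt2 was at -0.92 ± 0.14. The list's median was -0.41 (camera adjusted p = 8.8e-07, adjusted p = 0.241 with an estimated correlation), -0.40 on slide 1 and -0.55 on slide 3. In the oxidative phosphorylation list 11 of 63 genes fell and 1, Ndufb3, chosen after its value was seen, rose, over all genes and adjusted over the list alone. Ndufa10 fell by 0.96 ± 0.11 and Uqcrb was at -0.49 ± 0.07. Its median was -0.14 (camera adjusted p = 0.0182, adjusted p = 0.732 with an estimated correlation), but 0.05 on slide 1 against -0.28 on slide 3, and 0.07 with scaling between arrays. With Cy5 brightness as a covariate it was -0.47 (camera adjusted p = 8.9e-19).

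Endothelial markers fell together: 11 of 14 fell and none rose, over all genes and adjusted over the list alone. Their median was -0.57 (camera adjusted p = 4.76e-07, adjusted p = 0.263 with an estimated correlation), -0.57 on slide 1 and -0.53 on slide 3. The vascular endothelial growth factor receptor Flt1 fell by 1.17 ± 0.19 (adjusted p = 0.000867) and endoglin, Eng, was at -0.65 ± 0.10. Of 19 calcium handling and ion channel genes 12 fell and none rose (14 and 0 adjusted over the list alone). Their median was -0.66 (camera adjusted p = 2.89e-06, adjusted p = 0.263 with an estimated correlation), -0.77 on slide 1 and -0.43 on slide 3, and -0.27 with Cy5 brightness as a covariate. The potassium channel gene Kcnq1 fell by 1.49 ± 0.22 (adjusted p = 0.000467), and Kcne1, its accessory subunit, was at least 2.53-fold lower, as it was not above background on any double null array.

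Of 33 extracellular matrix genes 11 rose and 2 fell (13 and 2 adjusted over the list alone). The rises included Thbs4 (1.80 ± 0.29), Ccn2 and lumican, Lum (0.74 ± 0.19), and the falls were of the basement membrane collagens Col4a1 and Col4a2, chosen after their values were seen. The list's median was 0.47 (camera adjusted p = 0.000947, adjusted p = 0.603 with an estimated correlation), 0.55 on slide 1 and 0.31 on slide 3. It was -0.35 with median centring and -0.0026 with Cy5 brightness as a covariate. In the proteasome list 10 of 32 genes rose and none fell (11 and 0 adjusted over the list alone), with Psmd14 at 0.46 ± 0.11 and Psma2 at 0.42 ± 0.11. Its median was 0.19 (camera adjusted p = 0.0134, adjusted p = 0.491 with an estimated correlation), 0.13 on slide 1 and 0.17 on slide 3, and -0.93 with median centring. Heat shock genes rose in 5 of 11 cases (6 adjusted over the list alone), with Hsp90aa1 at 1.23 ± 0.15 (adjusted p = 0.000154) and Hspb1 at 0.90 ± 0.13. The mitochondrial chaperone gene Hspd1, chosen after its value was seen, was the 1 fall. The heat shock median was 0.33 (camera adjusted p = 0.0134, adjusted p = 0.263 with an estimated correlation), 0.62 on slide 1 and 0.41 on slide 3, and -0.62 with median centring.

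The series names E2F1-mediated expression, so E2F targets were a list of their own. Of 38 E2F targets and DNA replication genes 4 rose and 1 fell, over all genes and adjusted over the list alone. The rises were of Tfdp1, the E2F dimerisation partner (0.52 ± 0.10, adjusted p = 0.00356), and of Rfc4, Rfc5 and Prim1, replication genes chosen after their values were seen. The fall was of the uracil glycosylase Ung (-0.75 ± 0.17, adjusted p = 0.00758). The list's median was 0.24 (camera adjusted p = 0.00204, adjusted p = 0.683 with an estimated correlation), 0.38 on slide 1 and 0.13 on slide 3. It was -0.37 with median centring and -0.03 with Cy5 brightness as a covariate. Of 13 mitosis genes 1, Cenpa, rose (5 adjusted over the list alone); its adjusted p was up to 0.107 when single arrays were left out. The mitosis median was 0.49 (camera adjusted p = 0.00467, adjusted p = 0.615 with an estimated correlation), 0.69 on slide 1 and 0.22 on slide 3. It was -0.36 with median centring and -0.07 with Cy5 brightness as a covariate. E2f1 was not tested, since its 2 probes were well above background on 0 and 2 arrays. The cell cycle inhibitor Cdkn1a was at 0.09 ± 0.15 (adjusted p = 0.697), but at -0.56 with median centring and -0.38 with the Feature Extraction log ratio.

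**Figure D4:**
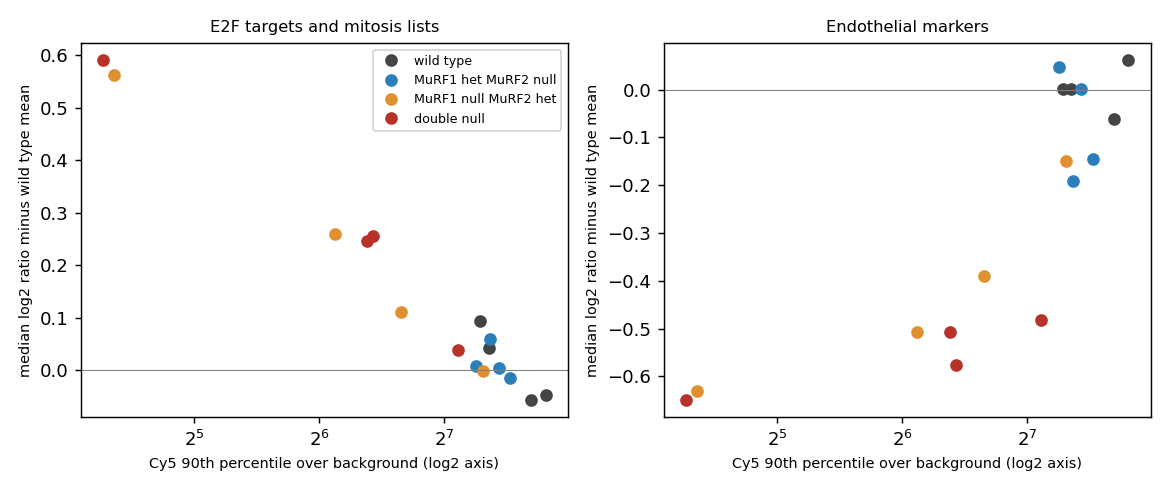
Median log2 ratio of the E2F target and mitosis lists (left) and of the endothelial markers (right) on each array, minus the wild type mean, against the upper decile of Cy5 signal over background on a log2 axis. Points are arrays, coloured by genotype.

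In all, 2750 of 12331 genes changed in double null hearts, 1265 up and 1485 down, with 72 over 2-fold higher and 142 over 2-fold lower. On slide 1 alone limma called 0 genes (2628 at an unadjusted p under 0.05) and on slide 3 alone 2351 genes, of which 2144 (91.2%) differed in the same direction on slide 1. With slide as a block 2985 genes passed. The count was 1676, 1555 and 1805 without wild type 2, 3 and 4, the arrays that moved it over 1.5 times. It was 6894 with median centring, 6628 with array weights and 1403 with a strict filter. Among the genes named here that rose, Trim54, Myl7, Ndufb3, Rfc4, Rfc5, Prim1, Tfdp1, Cenpa, Myl4, Cryab, Psmd14, Psma2, Lum, Hsp90aa1 and Hspb1 were under 0 with median centring. Of the 11 lists that passed, 6 passed without each array in turn. Without double null 2 the atrial, E2F and mitosis lists did not (medians 0.48, 0.14 and 0.28, adjusted p = 0.0679, 0.0689 and 0.0513). The fetal list did not pass without double null 3 (0.0557), nor oxidative phosphorylation without double null 3 or 4 or wild type 1 (up to 0.509). The oxidative phosphorylation median was -0.06 without double null 3 and -0.23 without double null 2.

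The comparison of MuRF1 null MuRF2 het with wild type hearts asks what remains altered when 1 MuRF2 allele is left. Myh7 was at 1.51, Nppa at 0.49, Nppb at -0.14 and Myh6 at -0.63 here, and none of the 4 passed (adjusted p = 0.222, 0.416, 0.823 and 0.225). With median centring Nppa and Myh7 were under 0, and Nppb was above 0 with the Feature Extraction log ratio. Hyi, which encodes hydroxypyruvate isomerase, rose 2.51-fold (1.33 ± 0.13, adjusted p = 7e-05), the glutathione transferase Gsta1 rose by 1.22 ± 0.20 (adjusted p = 0.0145) and cytochrome b5, Cyb5a, by 0.75 ± 0.10 (adjusted p = 0.00228). Kcne1 fell by 1.13 ± 0.15 (2.19-fold, adjusted p = 0.00174). The other large rises were of Wif1, Aqp8, Hmgn2, Ppt1, Gsta2, Pts and Twf2, and the other large falls of Nipal3, Ptprb, Nedd4, Klhdc8a, Flt1, Cish and St3gal3, with adjusted p up to 0.0498.

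Endothelial markers were lower here too. Of 14, Flt1 alone fell over all genes (-0.86 ± 0.19, adjusted p = 0.042) and 11 fell adjusted over the list alone. Their median was -0.44 (camera adjusted p = 3.37e-07, adjusted p = 0.683 with an estimated correlation), and -0.28 with Cy5 brightness as a covariate. Relative to the wild type mean it was -0.63, -0.15, -0.51 and -0.39 on MuRF1 null MuRF2 het 1, 2, 3 and 4. Of 19 calcium handling and ion channel genes Kcne1 alone fell (3 adjusted over the list alone). Their median was -0.35 (camera adjusted p = 0.00273, adjusted p = 0.683 with an estimated correlation), and 0.03 with Cy5 brightness as a covariate (camera adjusted p = 0.925). No E2F target, mitosis or adipocyte marker passed, over all genes or adjusted over the list alone, while the lists' medians of 0.21, 0.34 and 0.65 did (camera adjusted p = 0.000426, 0.00273 and 0.00273, adjusted p = 0.683 with an estimated correlation for each). With median centring these were -0.42, -0.35 and -0.32, and with Cy5 brightness as a covariate -0.03, -0.12 and -0.02, while the E2F median was -0.01 with the Cy5 channel alone.

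In all, 127 genes changed, 39 up and 88 down. The count was 60, 28, 27 and 23 without wild type 1, 2, 3 and 4, and 29, 1509, 30 and 31 without MuRF1 null MuRF2 het 1, 2, 3 and 4. It was 22 with the Feature Extraction log ratio and the series matrix values and 7379 with median centring. Of the 24 genes examined one by one that passed, 7 passed without each array in turn, namely Trim63, Hyi, Gsta1, Cyb5a, Kcne1, Clic4 and Fuca1, and the other 17 had adjusted p of up to 0.151. Hmgn2, Ppt1, Cyb5a, Pts and Twf2 were under 0 with median centring. Of the 5 lists that passed, the calcium and channel list and the mitosis list did not pass without MuRF1 null MuRF2 het 1 (medians -0.13 and 0.22, adjusted p = 0.0661 and 0.0662). Without that array the adipocyte median was 0.33 and the E2F median 0.12, and both passed.

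Several of these genes lie near Trim63 on chromosome 4. Of 210 tested genes within 10 Mb of Trim63, 8 (3.81%) passed, against 0.98% of the others (odds ratio 4.00, Fisher exact p = 0.00148). They included Clic4, a chloride channel (-0.78 ± 0.12, adjusted p = 0.0103), Nipal3, Pnrc2, Eya3, Fuca1, a fucosidase (0.60 ± 0.08, adjusted p = 0.0034), Hmgn2 and Tmem51. These are named because they lie there, Clic4, Pnrc2, Eya3, Fuca1 and Tmem51 after their values were seen. Hyi, Ppt1 and St3gal3 lie on the same chromosome more than 10 and less than 20 Mb from Trim63. Tmem51, Fuca1 and Hmgn2 were under 0 with median centring. With Trim55, fixed beforehand as the second locus, included, the odds ratio was 3.52 (Fisher exact p = 0.00314), and no gene near Trim55 passed. The odds ratio for Trim63 was 2.57 (Fisher exact p = 0.00836) in MuRF1 het MuRF2 null and 1.11 (Fisher exact p = 0.505) in double null hearts, each against wild type. In the latter it was 1.48 within 20 Mb (Fisher exact p = 0.00111).

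The comparison of MuRF1 het MuRF2 null with wild type hearts asks the converse, what changes with 1 MuRF1 allele left and no MuRF2. Pdk4, the kinase that blocks pyruvate dehydrogenase, fell 3.15-fold (-1.66 ± 0.25, adjusted p = 0.00508). The lipase gene Pnpla2 (-0.87 ± 0.15, adjusted p = 0.00949) and the lipid droplet gene Plin4 fell too. The potassium channel gene Kcnj14 was at least 4.23-fold lower, being above background on no MuRF1 het MuRF2 null array (adjusted p = 0.00949). Other large falls were of Pirb, Cox7c, Plbd1, Map3k6 and Mpst. Hyi rose by 0.93 ± 0.13 (adjusted p = 0.0038), the syndecan Sdc2 by 0.68 ± 0.10 (adjusted p = 0.0038) and the clock output gene Dbp by 1.03 ± 0.25 (adjusted p = 0.0435). Other large rises were of Hmgn5, Ppp1r27, Slc6a6, Tmem51, Hmgn2, Pip4p2 and Kmt5a.

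Of 29 fatty acid oxidation genes 3 fell and none rose (6 and 0 adjusted over the list alone), Pdk4, Etfdh and Acadl, the last chosen after its value was seen. The list's median was -0.23 (camera adjusted p = 0.00692, adjusted p = 0.559 with an estimated correlation) and 0.03 with the Cy5 channel alone, where Acadl was at 0.02. Acadl did not pass in any of 8 fits without single arrays (adjusted p up to 0.131). Of 14 macrophage markers 2 fell, Adgre1 (-0.62 ± 0.15) and C1qc (-0.41 ± 0.10), over all genes and adjusted over the list alone. When single arrays were left out, C1qc did not pass in any of 8 fits (adjusted p up to 0.161) and Adgre1 did not in 7 of 8 (up to 0.111). C1qc lies 2.57 Mb from Trim63. The macrophage median was -0.18 (camera adjusted p = 0.00454, adjusted p = 0.675 with an estimated correlation). In the circadian list Dbp rose among 13 (3 rose and 1 fell adjusted over the list alone), and in the interferon list Ifit2, at least 1.26-fold higher, rose among 16 (1 adjusted over the list alone). The circadian median was 0.23 (camera adjusted p = 0.0173, adjusted p = 0.559 with an estimated correlation) and -0.03 with median centring. The interferon median was 0.19 (camera adjusted p = 0.00454, adjusted p = 0.877 with an estimated correlation) and -0.03 with median centring, a setting that moved the median of all genes by -0.34.

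In all, 247 genes changed, 82 up and 165 down. The count was 115, 69 and 99 without wild type 1, 2 and 4, and 88, 99, 139 and 109 without MuRF1 het MuRF2 null 1, 2, 3 and 4. It was 23 with the Feature Extraction log ratio and the series matrix values, 2084 with only these 2 groups in the fit and 616 with the Cy5 channel alone. The reference channel differed too: Cy3 alone gave 6761 genes, and 185 of the 247 were among them, 148 with the opposite sign to the ratio. Of the 26 genes examined one by one that passed, 10 passed without each array in turn, among them Pdk4, Kcnj14, Pnpla2, Hyi, Sdc2, Pirb and Cox7c, and the other 16 had adjusted p of up to 0.161, while Hmgn5 and Pip4p2 were under 0 with the Cy5 channel alone. Of the 4 lists that passed, 3 passed without each array in turn, and the circadian list did not without wild type 1 (adjusted p = 0.146).

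The comparison of double null with MuRF1 null MuRF2 het hearts sets no MuRF2 allele against 1, all without MuRF1, but the 2 groups lay on different slides. Nppa was at least 5.31-fold higher (2.41 ± 0.36, adjusted p = 0.0114) and Nppb 3.68-fold higher (1.88 ± 0.33, adjusted p = 0.0261) in double null hearts. The other large rises were of Ccn2 (2.18 ± 0.39, adjusted p = 0.0261), Acta1 (1.59 ± 0.28, adjusted p = 0.0253) and Lman1l. Myh7 was at 2.93 and did not pass (adjusted p = 0.101), but passed without double null 1 (3.84). The falls were led by Lrtm1, Fndc5 (-1.11 ± 0.13, adjusted p = 0.00341), the thiolase gene Acaa2 (-1.06 ± 0.20, adjusted p = 0.0381), Cish and the leucine catabolism gene Mccc1.

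Fatty acid oxidation genes fell in 7 of 29 cases and none rose (17 and 0 adjusted over the list alone), with Eci1 at -0.82 ± 0.12 and Hadh at -0.76 ± 0.13. Their median was -0.37 (camera adjusted p = 8.02e-19, adjusted p = 0.0049 with an estimated correlation). Heat shock genes rose in 3 of 11 cases, Hsp90aa1 (1.01 ± 0.15), Hspb1 and, chosen after its value was seen, Hspa8 (5 rises and 1 fall adjusted over the list alone). The heat shock median was 0.28 (camera adjusted p = 1.05e-05, adjusted p = 0.0107 with an estimated correlation). These 2 lists were the ones that passed with an estimated correlation in any comparison. In the fetal list Nppa, Acta1, Ccn2 and Nppb rose and Atp2a2 (-0.73 ± 0.14) fell among 19 (9 and 2 adjusted over the list alone). The fetal median was 0.44 (camera adjusted p = 2.77e-05, adjusted p = 0.194 with an estimated correlation). Ndufa10 alone fell among 63 oxidative phosphorylation genes (12 adjusted over the list alone). Their median was -0.22 (camera adjusted p = 5.68e-11, adjusted p = 0.503 with an estimated correlation). Atp2a2 alone fell among 19 calcium handling and ion channel genes (3 adjusted over the list alone), whose median was -0.29 (camera adjusted p = 1.05e-05, adjusted p = 0.328 with an estimated correlation). Smaller shifts passed for the extracellular matrix, endothelial, interferon and proteasome lists, with medians of 0.13, -0.17, -0.17 and 0.10 (adjusted p = 0.634, 0.634, 0.634 and 0.503 with an estimated correlation). Among their members Ccn2 alone passed, over all genes and adjusted over the list alone.

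In all, 43 genes changed, 20 up and 23 down. The count was 114, 196, 7 and 3 without double null 1, 2, 3 and 4, and 360, 18, 4 and 3 without MuRF1 null MuRF2 het 1, 2, 3 and 4. In limma 0 genes passed with median centring (184 at an unadjusted p under 0.05) and 0 with only these 2 groups in the fit (566). The count was 1561 with array weights, 481 without the 2 dimmest arrays, 351 with Cy5 brightness as a covariate and 308 with the Cy5 channel alone. Of the 35 ways to part these 8 arrays into 4 and 4, 5 gave 43 genes or more. Of 17 genes examined one by one that passed, only Fndc5 passed without each array in turn, the others having adjusted p of up to 0.170.

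Of the 9 lists that passed here, 5 passed without each array in turn. The extracellular matrix and fibrosis list did not pass without double null 2 (median -0.08, adjusted p = 0.451), and its median ran from there to 0.33, without MuRF1 null MuRF2 het 1. It was 0.23 and 0.21 without double null 1 and 3 and -0.00572 and 0.09 without MuRF1 null MuRF2 het 2 and 4. The interferon list did not pass without double null 2 or MuRF1 null MuRF2 het 2 (-0.03 without the latter, adjusted p = 0.614). The endothelial list did not without double null 1 or 2 or MuRF1 null MuRF2 het 2 (-0.09 without the latter, adjusted p = 0.450). The proteasome list did not without double null 1 or 3 or MuRF1 null MuRF2 het 1 or 2 (0.05 without double null 1, adjusted p = 0.145), and it was at 0.06 without MuRF1 null MuRF2 het 4. Among the lists that did pass, the heat shock median was 0.50 and 0.17 without double null 2 and 4. The calcium and channel median was -0.19 and -0.16 without double null 2 and MuRF1 null MuRF2 het 2. The oxidative phosphorylation median was -0.36 and -0.11 without double null 2 and 3 and -0.12 without MuRF1 null MuRF2 het 1.

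Double null hearts were also compared with MuRF1 het MuRF2 null hearts, which retain 1 MuRF1 allele. Nmrk2 was higher by 2.81 ± 0.47 (adjusted p = 0.000885; 3.40 without double null 2), Rbp7 6.58-fold and Ccn2 6.16-fold (2.62 ± 0.39) in double null hearts. The sarcomere protein gene Myot was 5.45-fold higher (2.45 ± 0.30, adjusted p = 0.000119) and Abra, an actin-binding activator of serum response factor, 4.12-fold higher. After Trim63 (-2.66 ± 0.14, 6.33-fold, adjusted p = 2.84e-08), the probe for titin, Ttn, was 5.37-fold lower (-2.42 ± 0.34, adjusted p = 0.000269), followed by Crhr2, Ppm1k and the ubiquitin ligase gene Nedd4. Trim54 rose by 0.50 ± 0.11 (adjusted p = 0.00565) but was at -0.23 with median centring. Nppa rose by at least 2.02 ± 0.36.

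Of 19 calcium handling and ion channel genes 12 fell and 1 rose (14 and 1 adjusted over the list alone). The gap junction gene Gja1 was at -1.28 ± 0.20 and Kcne1 at least 2.01-fold lower. The channel median was -0.80 (camera adjusted p = 7.11e-06, adjusted p = 0.51 with an estimated correlation), and -0.38 with Cy5 brightness as a covariate. Of 14 endothelial markers 10 fell and none rose, over all genes and adjusted over the list alone, with Kdr at -1.24 ± 0.19 and Erg at -0.79 ± 0.14. The endothelial median was -0.45 (camera adjusted p = 2.92e-05, adjusted p = 0.511 with an estimated correlation). Fatty acid oxidation genes fell in 14 and rose in 3 of 29 cases, over all genes and adjusted over the list alone, with Hadh at -0.82 ± 0.13 and Pdk4 at 1.86 ± 0.25. The fatty acid oxidation median was -0.31 (camera adjusted p = 0.0057, adjusted p = 0.511 with an estimated correlation). Heat shock genes rose in 6 and fell in 1 of 11 cases, over all genes and adjusted over the list alone, with Hsp90aa1 at 1.58 ± 0.15 and Hspb1 at 1.38 ± 0.13. The heat shock median was 0.58 (camera adjusted p = 0.0129, adjusted p = 0.51 with an estimated correlation), and -0.07 with median centring. Of 33 matrix genes 12 rose and 1 fell (13 and 1 adjusted over the list alone), Tnc (0.73 ± 0.14) among the rises. The matrix median was 0.40 (camera adjusted p = 0.00115, adjusted p = 0.624 with an estimated correlation), but -0.10 with the Cy5 channel alone and -0.04 with the Feature Extraction log ratio. With Cy5 brightness as a covariate it was 0.10 and did not pass (camera adjusted p = 0.167).

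Cell cycle, proteasome, immune, circadian and atrial lists passed too. Of 13 mitosis genes 4 rose (7 adjusted over the list alone), Kif20a by 1.01 ± 0.18, with a median of 0.56 (camera adjusted p = 0.0032, adjusted p = 0.624 with an estimated correlation). Of 38 E2F targets 8 rose and 2 fell, over all genes and adjusted over the list alone, with Tfdp1 at 0.57 ± 0.10 and Ung at -0.83 ± 0.17. The E2F median was 0.18 (camera adjusted p = 0.0259, adjusted p = 0.728 with an estimated correlation), but -0.09 with median centring, -0.07 with the Feature Extraction log ratio and -0.02 with Cy5 brightness as a covariate. Proteasome genes rose in 8 and fell in 2 of 32 cases, over all genes and adjusted over the list alone, with Psmc5 and Psma3 both at 0.46. The proteasome median was 0.16 (camera adjusted p = 0.0311, adjusted p = 0.624 with an estimated correlation), but -0.46 with median centring. Macrophage markers rose in 5 of 14 cases (6 adjusted over the list alone), Lgals3 by 1.31 ± 0.20, with a median of 0.17 (camera adjusted p = 0.0426, adjusted p = 0.624 with an estimated correlation). Circadian genes fell in 4 and rose in 1 of 13 cases, over all genes and adjusted over the list alone, with Hlf at -1.29 ± 0.21 and Nr1d1 at -1.10 ± 0.22. The circadian median was -0.43 (camera adjusted p = 0.0129, adjusted p = 0.511 with an estimated correlation). Interferon genes fell in 4 of 16 cases, over all genes and adjusted over the list alone, with Gbp2 at -1.15 ± 0.20. The interferon median was -0.30 (camera adjusted p = 0.00256, adjusted p = 0.624 with an estimated correlation). Nppa alone rose among 6 atrial markers, over all genes and adjusted over the list alone. The atrial median was 0.59 (camera adjusted p = 0.0426, adjusted p = 0.624 with an estimated correlation), but -0.04 with median centring and -0.0083 with Cy5 brightness as a covariate.

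With Cy5 brightness as a covariate 6 of these lists did not pass, nor did the matrix list. The camera adjusted p was then 0.432 for mitosis (median 0.03), 0.786 for E2F targets, 0.0576 for macrophage markers (median 0.22), 0.0906 for circadian (median -0.27) and interferon genes (median -0.16) and 0.910 for atrial markers.

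In all, 3254 genes changed, 1692 up and 1562 down, and no single array moved the count over 1.5 times. Median centring gave 872, a strict filter 1512 and array weights 6794. In the reference channel alone 7023 genes differed, and 1964 of the 3254 were among them, 1192 with the opposite sign. Tnc was under 0 with the Cy5 channel alone and well above background on 1 double null array, and Psma3 was under 0 with median centring. Of the 12 lists that passed, 8 passed without each array in turn. The atrial and E2F lists did not pass without double null 2 (medians 0.21 and 0.08, adjusted p = 0.175 and 0.326), where the mitosis median was 0.33 and the macrophage median 0.25. The macrophage and proteasome lists did not pass without double null 1 or 3 or MuRF1 het MuRF2 null 4 (adjusted p up to 0.107 and 0.0756).

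The last comparison set MuRF1 null MuRF2 het against MuRF1 het MuRF2 null hearts. Pdk4 was 3.67-fold higher (1.88 ± 0.25, adjusted p = 0.00182), and Rbp7 4.06-fold higher (2.02 ± 0.39, adjusted p = 0.00955) in the hearts without MuRF1. Abat, a transaminase gene, was higher by 2.70 ± 0.71 (adjusted p = 0.0315; 3.32 and 1.87 without MuRF1 null MuRF2 het 2 and 3, adjusted p up to 0.0915), and Krt1 and Myot rose too. Trim63 fell by 2.58 ± 0.14 (5.97-fold, adjusted p = 4.68e-08), the titin probe Ttn by 2.11 ± 0.34 (adjusted p = 0.00378) and the smooth and cardiac muscle coactivator Myocd by 1.56 ± 0.21 (adjusted p = 0.00182), followed by Nebl and Dhrs7c.

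Each of the 8 lists that passed here had an adjusted p of 0.735 with an estimated correlation, and none passed with it. Endothelial markers fell in 7 of 14 cases (10 fell and 1 rose adjusted over the list alone), with Kdr at -0.80 ± 0.19 and Tek at -0.47 ± 0.12 (median -0.38, camera adjusted p = 0.000341). Calcium handling and ion channel genes fell in 6 of 19 cases with 1 rise (9 fell and 3 rose adjusted over the list alone). Kcne1 fell by 1.03 ± 0.15 and Gja1 was at -0.97 ± 0.20 (list median -0.50, camera adjusted p = 0.003). Macrophage markers rose in 4 of 14 cases (8 adjusted over the list alone), Lyz2 by 0.98 ± 0.21 and Ptprc by 0.29 ± 0.07 (median 0.30, camera adjusted p = 0.00222). Circadian genes fell in 2 of 13 cases, Nr1d1 and Hlf (2 fell and 1 rose adjusted over the list alone, median -0.28, camera adjusted p = 0.0293). Kif20a alone rose among 13 mitosis genes, over all genes and adjusted over the list alone (median 0.39, camera adjusted p = 0.00295). Among 38 E2F targets Tfdp1, Mcm7 and, chosen after its value was seen, Ccna2 rose (6 adjusted over the list alone, median 0.19, camera adjusted p = 0.0187). Uqcrfs1 alone rose among 63 oxidative phosphorylation genes, over all genes and adjusted over the list alone (median 0.29, camera adjusted p = 0.0137). Of 9 adipocyte markers none passed, over all genes or adjusted over the list alone (median 0.65, camera adjusted p = 0.0309). The E2F median was -0.07 with median centring, -0.06 with the Feature Extraction log ratio and -0.02 with the Cy5 channel alone. The oxidative phosphorylation median was -0.72 with median centring, and with Cy5 brightness as a covariate it was -0.06, the adipocyte median -0.02 and the E2F median -0.02. With that covariate the mitosis median was 0.0065 (camera adjusted p = 0.897), the calcium and channel median -0.09 (adjusted p = 0.230) and the circadian median -0.22 (adjusted p = 0.230). The camera adjusted p was then 0.393 for E2F targets, 0.173 for oxidative phosphorylation and 0.689 for adipocyte markers, so of these 8 lists only the endothelial and macrophage lists passed (medians -0.25 and 0.26, adjusted p = 0.0284 and 0.00854). Krt1, Tfdp1 and Mcm7 were under 0 with the Cy5 channel alone, and Uqcrfs1 with median centring. In MuRF1 null MuRF2 het hearts Krt1 and Ptprc were well above background on 1 array and Ccna2 on none, so their rises rest on dim signals.

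In all, 1052 genes changed, 566 up and 486 down. The array groups lay on different slides, 6843 genes differed in the reference channel alone, and 687 of the 1052 were among them, 518 with the opposite sign. The count was 407, 2107, 352 and 653 without MuRF1 null MuRF2 het 1, 2, 3 and 4, and 221, 339, 566 and 346 without MuRF1 het MuRF2 null 1, 2, 3 and 4. It was 290 with the Feature Extraction log ratio, 353 with median centring, 436 with a strict filter and 1843 with the Cy5 channel alone. Of the 23 genes examined one by one that passed, 11 passed without each array in turn, the others having adjusted p of up to 0.104. Of the 8 lists that passed, 4 passed without each array in turn. The adipocyte, E2F and oxidative phosphorylation lists did not without MuRF1 null MuRF2 het 1 (medians 0.36, 0.10 and 0.12, adjusted p = 0.238, 0.253 and 0.289), where the mitosis median was 0.26. The circadian list did not without MuRF1 null MuRF2 het 1 or 2 (adjusted p up to 0.121).

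The 3 comparisons against wild type share the wild type arrays, so the covariance of their changes was set against 100 simulations that share them. Double null and MuRF1 null MuRF2 het hearts had 122 genes changed the same way, 36 up and 86 down, and 0 in opposite directions. Independent lists would share 4.00 up and 10.6 down. Across genes their changes had a covariance of 0.0880 against 0.0108 in the simulations, and a correlation of 0.873 against 0.4996. Both groups were dim in Cy5, which the simulations do not share. The change predicted from brightness correlated at 0.668 with the observed change in double null hearts, so the likeness is not separated from shared dimness. With 2 wild type arrays for each comparison the covariance was 0.0833 and the shared genes 8 on average over 6 splits (3 to 19). Double null and MuRF1 het MuRF2 null hearts shared 92 genes, 22 up and 70 down, with 12 in opposite directions (covariance 0.0196 against 0.0108 simulated, correlation 0.257 against 0.499; 3.17 genes on average with split wild type arrays, 0 to 12). The 2 heterozygous groups shared 19 genes, 4 up and 15 down (covariance 0.0166 against 0.0108, correlation 0.29996 against 0.4998; 0.333 genes on average with split wild type arrays, 0 to 1).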

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

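The slide test for the double null gene count, the brightness covariate and the 127-gene cutoff near Trim63 were chosen after the results were seen.

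In 23 of 387 groups of 4 arrays, 1 array lay far from the other 3 by Dixon's test at its 95% critical value. The number given for each is its gap to the nearest other array over the range of the group. Chance gives about 1 in 20 groups, here 19.35. Double null 2 stood apart for 3 genes, high for Trim55 (0.939) and Myl4 (0.892) and low for Ppm1k (0.937), and double null 3 was high for Ifit2 (0.874). Wild type 1 was high for Nmrk2 (0.851) and low for Ccn1 (0.908) and Plin4 (0.848). Wild type 2 was high for Nipal3 (0.962), wild type 3 low for Hyi (0.833), Gsta1 (0.863), Aqp8 (0.861) and Atf3 (0.965), and wild type 4 low for Fndc5 (0.860). Among MuRF1 null MuRF2 het arrays, array 1 was high for Hspb1 (0.847), array 2 low for Acta1 (0.884) and high for Ttn (0.846), array 3 low for Trim54 (0.919) and array 4 low for Tmem51 (0.963). Among MuRF1 het MuRF2 null arrays, array 1 was high for Ptprc (0.919), array 2 low for Ppp1r27 (0.837) and high for Kcne1 (0.842), and array 3 high for Nppa (0.928) and Hsp90aa1 (0.838).

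The reference was meant to be the same on every array, yet its Cy3 signal alone, which no ratio comparison uses by itself, differed for 6761 genes between MuRF1 het MuRF2 null and wild type arrays. The corresponding numbers were 177 for double null and 38 for MuRF1 null MuRF2 het against wild type, and 22 for double null against MuRF1 null MuRF2 het. The MuRF1 het MuRF2 null arrays were on a slide of their own and were read with another version of Feature Extraction, so slide, software and genotype cannot be told apart for this group. No explanation of this difference was tested.

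For each comparison the 8 arrays were also parted in all 35 ways into 4 and 4. For double null against wild type, 1 split, the real one, gave 2750 genes, and the highest of the others gave 1 gene. The same held for MuRF1 null MuRF2 het against wild type (1 split, 127 genes, highest other 2) and for MuRF1 het MuRF2 null against wild type (1 split, 247 genes, highest other 0). It held for double null against MuRF1 het MuRF2 null (1 split, 3254 genes, highest other 1). It also held for MuRF1 null MuRF2 het against that group (1 split, 1052 genes, highest other 0). With 35 splits chance is not excluded for these 5 counts. For double null against MuRF1 null MuRF2 het, 5 of 35 splits gave 43 genes or more, so chance cannot be excluded. There the highest other split gave 2478 genes and set double null 1 and 2 and MuRF1 null MuRF2 het 1 and 3 against the rest. That many genes point to a structure of the samples other than genotype, and these 4 arrays include the 2 dimmest.

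The first pattern weighed was the number of genes that differed between double null and wild type hearts, 2750. Double null arrays were dimmer in Cy5, by -1.49 on a log2 scale. From the slope on brightness within the other 3 groups, a shift of at least 50% of the observed change, with its sign, was predicted for 37.1% of these genes, and for 51.2% of all tested genes. The bounds set beforehand were 50% for brightness as the cause and 25% against it, so brightness stays open for part of the genes, and a fit with brightness as a covariate gave 1966 genes. Slide is argued against, since 91.2% of the genes that passed on slide 3 alone differed in the same direction on slide 1, with no array shared. On slide 1 alone limma called 0 genes, with 2628 at an unadjusted p under 0.05. Loss of both genes is the other open explanation, and the 2 cannot be told apart for genes whose change goes along with brightness.

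The second pattern was the higher E2F target and mitosis lists in double null hearts, with a median of 0.30 over 51 members. The median predicted from brightness was 0.29, which is 98.8% of it. With brightness as a covariate the median was -0.03, or -11.4% of its value without, and camera gave an adjusted p of 0.889 for the E2F and 0.692 for the mitosis list. That reached the bound set against a change in the hearts that lack both genes, and lower Cy5 brightness is a candidate explanation. However, every double null array was dimmer than every wild type array. The upper decile of Cy5 signal over background was 19.3 to 138 in double null and 156 to 224 in wild type. A change in the hearts that goes along with brightness therefore cannot be told apart from brightness here. The covariate test was repeated without each array in turn, without the 2 dimmest arrays and without the slide of the MuRF1 null MuRF2 het arrays. Its median ran from -0.06 to -0.0017, or from -23.3% to -0.47% of the value without the covariate. Without MuRF1 null MuRF2 het 1, the dimmest array outside the double null group, the predicted median was 0.30 and the covariate median -0.03. By Cy5 level the members had a mean rank at percentile 43.0 of the tested genes. The test covers the lists' medians and leaves open single members such as Tfdp1.

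The third pattern was the excess of genes near Trim63 among those that differed between MuRF1 null MuRF2 het and wild type hearts. The 8 genes within 10 Mb gave an odds ratio of 4.00 (Fisher exact p = 0.00148). A chromosome segment carried along with the targeted MuRF1 allele may be the source, as a hypothesis found and tested on the same data. The labels call the mice strain-matched, and the strain of the targeted cells is not given in the sources used here. Lower Cy5 brightness is argued against, since it predicted at least 50% of the change for 0% of the 8 genes. All 8 (100%) changed the same way in double null against wild type on both shared slides. That reached the bound set against slide as the cause, but both comparisons use the wild type arrays and the MuRF1 null MuRF2 het arrays lie on 1 slide, so slide cannot be told apart from genotype. In double null against wild type the odds ratio was 1.11 (Fisher exact p = 0.505), and 1.48 within 20 Mb (Fisher exact p = 0.00111). Of its 127 genes with the smallest p, 6 lay within 10 Mb (odds ratio 2.89, Fisher exact p = 0.0225). With the wild type arrays shared, this is no independent support.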

How the results depend on the processing

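The fits without the 2 dimmest arrays, with a normexp offset of 0 and with Cy5 brightness as a covariate, and those of the lists without single arrays, were chosen after the data were examined. Except where said, the cause of a difference was not tested.

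Recomputing 223 results for named genes gave 5497 values, of which 4413 kept their direction and their side of the threshold, and 45 values of results that had passed turned direction. Of the 223 gene results, 220 were kept with every probe on its own, 218 with array weights, 217 without the 2 dimmest arrays, 214 with an intensity trend, 209 with no background subtraction, 200 with scaling between arrays, 191 with the replicate block, 183 with no filter, 175 with brightness as a covariate, 175 with only the 2 groups, 160 with an offset of 0, 157 with Cy5 alone, 127 with the Feature Extraction log ratio and with the series matrix values, and 104 with median centring. With a strict filter 141 of 145 were kept, and with slide as a block 85 of 85. With slide as a random block 138 of 138 were kept, but its correlation was -0.00816, so it removed nothing that slide and genotype share.

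For double null against wild type (2750 genes) the count was 6894 with median centring, 6628 with array weights and 1403 with a strict filter, which tested fewer genes. Without single arrays it ranged from 1555 to 3611.

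For MuRF1 null MuRF2 het against wild type (127) it was 7379 with median centring, 2228 with array weights, 66 with the replicate block, 58 with Cy5 alone, 28 with an offset of 0, 27 with a strict filter, 22 with the Feature Extraction log ratio, 22 with the series matrix values and 16 with only the 2 groups. Without single arrays it ranged from 23 to 1509.

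For MuRF1 het MuRF2 null against wild type (247) it was 3004 with array weights, 2552 with median centring, 2084 with only the 2 groups, 1321 with brightness as a covariate, 1050 without the 2 dimmest arrays, 616 with Cy5 alone, 152 with the replicate block, 95 with an offset of 0, 23 with the Feature Extraction log ratio and 23 with the series matrix values. Without single arrays it ranged from 69 to 185.

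For double null against MuRF1 null MuRF2 het (43) it was 1561 with array weights, 481 without the 2 dimmest arrays, 351 with brightness as a covariate, 308 with Cy5 alone, 101 with an offset of 0, 87 with the Feature Extraction log ratio, 87 with the series matrix values, 76 with scaling, 23 with an intensity trend, 16 with the replicate block and 14 with no filter. In limma 0 genes passed with median centring (184 at an unadjusted p under 0.05) and 0 with only the 2 groups (566). Without single arrays it ranged from 3 to 360.

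For double null against MuRF1 het MuRF2 null (3254) it was 6794 with array weights, 1512 with a strict filter and 872 with median centring, and 2181 to 3785 without single arrays. For MuRF1 null MuRF2 het against MuRF1 het MuRF2 null (1052) it was 3166 with array weights, 1843 with Cy5 alone, 448 with an offset of 0, 436 with a strict filter, 353 with median centring, 290 with the Feature Extraction log ratio and 288 with the series matrix values, and 221 to 2107 without single arrays.

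Median centring turned the direction of these genes. In double null against wild type: Trim55 -0.76, Trim54 -0.69, Tfdp1 -0.063, Cenpa -0.10, Myl4 -0.32, Cryab -0.59, Psmd14 -0.62, Psma2 -0.98, Sqstm1 -0.39, Tcf21 -0.065, Lum -0.57, Ptprc -0.056, Retn -0.14, Hsp90aa1 -0.12, Hspb1 -0.39, Ccn1 -0.071, Asns -0.043, Cdkn1a -0.56, Myl7 -0.15, Ndufb3 -1.07, Rfc4 -0.35, Rfc5 -0.11, Prim1 -0.18, Ldha -1.09, Gabarapl1 -0.43, Bnip3l -0.59, Cnn1 -0.29, Tagln -0.50, Myh1 -0.25 and Atf3 -0.087. In MuRF1 null MuRF2 het against wild type: Hmgn2 -0.58, Ppt1 -0.10, Cyb5a -0.27, Pts -0.0075, Twf2 -0.63, Trim55 -0.43, Trim54 -0.94, Fuca1 -0.36, Tmem51 -0.30, Nppa -0.73 and Myh7 -0.070. In MuRF1 het MuRF2 null against wild type: Trim55 -0.20 and Trim54 -0.47. Against MuRF1 het MuRF2 null, in double null hearts: Trim54 -0.23 and Psma3 -0.030; in MuRF1 null MuRF2 het hearts: Trim55 -0.23, Trim54 -0.47 and Uqcrfs1 -0.22.

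With Cy5 alone these turned: Cdkn1a -0.029 in double null and Hmgn5 -0.064, Pip4p2 -0.34, Acadl 0.021 and Trim55 -0.90 in MuRF1 het MuRF2 null against wild type, Trim55 1.47 and Tnc -0.083 in double null against MuRF1 het MuRF2 null, and Krt1 -0.058, Tfdp1 -0.14 and Mcm7 -0.13 in MuRF1 null MuRF2 het against MuRF1 het MuRF2 null. In double null against wild type Cdkn1a was at -0.38 with the Feature Extraction log ratio, -0.38 with the series matrix values, -0.16 with brightness as a covariate and -0.053 without wild type 3 (up to 0.20, without wild type 1), and Trim55 at -0.091 with brightness as a covariate. In MuRF1 null MuRF2 het against MuRF1 het MuRF2 null, Trim55 was at -0.15 with brightness as a covariate. Nppb in MuRF1 null MuRF2 het against wild type, which had not passed, was at 0.0021 with no background subtraction, 0.49 with the Feature Extraction log ratio, 0.49 with the series matrix values, 0.15 with scaling, 0.20 with Cy5 alone, 0.42 with an offset of 0 and 0.36 with brightness as a covariate. It was at 0.17 without the 2 dimmest arrays, 0.063 without wild type 2 and 0.17 without MuRF1 null MuRF2 het 1. Trim63 in double null against MuRF1 null MuRF2 het was at 0.012 without MuRF1 null MuRF2 het 1 and at 0.020 without double null 3. Trim55 in double null against MuRF1 het MuRF2 null was at 0.031, 0.0074 and 0.028 without double null 1, 3 and 4.

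Of 162 list tests 49 passed. The total passing was 33 with fry, 20 with a strict filter and 2 with an estimated correlation. It was between 34 and 63 with the other alternatives run for all comparisons. Not all of these were among the 49. Direction and call were kept for 23 of the 49 with fry, 26 with median centring, 26 with Cy5 alone and 28 with brightness as a covariate. The number kept was 2 with an estimated correlation, 20 of 42 with a strict filter, and between 33 and 49 with the others. Of the 49, 29 passed without each array in turn. The E2F and mitosis lists turned with median centring, to -0.37 and -0.36 in double null and to -0.42 and -0.35 in MuRF1 null MuRF2 het against wild type. With brightness as a covariate they turned to -0.033 and -0.067 and to -0.033 and -0.12. The E2F list also turned against MuRF1 het MuRF2 null with brightness as a covariate, to -0.021 in double null and to -0.023 in MuRF1 null MuRF2 het hearts. With a strict filter its test in double null against MuRF1 het MuRF2 null turned down, with a median of 0.11 that stayed above 0. Adipocyte markers turned with brightness as a covariate in MuRF1 null MuRF2 het hearts, to -0.016 against wild type and -0.021 against MuRF1 het MuRF2 null. Oxidative phosphorylation turned with scaling in double null against wild type (0.075). In MuRF1 null MuRF2 het against MuRF1 het MuRF2 null it turned with median centring (-0.72, passing downward, camera adjusted p = 0.0217), an offset of 0 (-0.040) and brightness as a covariate (-0.063). In double null against MuRF1 het MuRF2 null the proteasome list turned with median centring (-0.46) and the matrix list with Cy5 alone (-0.10).

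With separate wild type arrays for each comparison, the overlaps of 122, 92 and 19 genes were 8, 3.17 and 0.333 on average, with 2 wild type arrays in place of 4. Within 20 Mb of Trim63 or Trim55 the odds ratio in double null against wild type was 1.32 (Fisher exact p = 0.0157). In double null against MuRF1 null MuRF2 het it was 1.15 within 10 Mb and 0 within 5 Mb. In double null against MuRF1 het MuRF2 null it was 0.859 within 10 Mb, 1.01 within 5 Mb and 1.10 within 20 Mb.

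Signal over background limits the 2 dimmest arrays most: 6028 and 6397 probes were well above background in Cy5, against 17382 on the brightest array.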

Other observations

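The list tests in this part were fixed before the data were examined, while the genes marked so were chosen after their values were seen. The comparison of double null with wild type hearts held further lists that did not pass as a whole, and they are given here as values.

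Of 22 glycolysis and glucose uptake genes 5 fell and 1, Ldha, chosen after its value was seen, rose (7 and 2 adjusted over the list alone; median -0.13, camera adjusted p = 0.0846). Phosphofructokinase, Pfkm, fell by 0.84 ± 0.15 (adjusted p = 0.00135) and hexokinase 2, Hk2, was at -1.12 ± 0.21 (adjusted p = 0.00222). Of 19 muscle atrophy and autophagy genes 3 rose and 3 fell (4 and 5 adjusted over the list alone; median -0.13, camera adjusted p = 0.652). The autophagy receptor gene Sqstm1 rose by 1.02 ± 0.12 (adjusted p = 0.000154) but was under 0 with median centring; Gabarapl1 and Bnip3l rose and Ulk1 and Foxo1 fell, all 4 chosen after their values were seen. In the MuRF family list Trim63 fell and Trim54 rose, so its median was 0.37 while its mean was -0.79 and its test pointed down (camera adjusted p = 0.655).

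Of 12 fibroblast markers Tcf21 (0.35 ± 0.08) and Lum (0.74 ± 0.19) rose, both under 0 with median centring (median 0.28, camera adjusted p = 0.0779). Of 10 smooth muscle and pericyte markers Smtn (-0.56 ± 0.14), Pdgfrb (-0.65 ± 0.20) and Rgs5 fell and Cnn1 and Tagln rose, the last 3 chosen after their values were seen; the median was 0.06, the mean -0.03 and the test pointed down (camera adjusted p = 0.877). Of 14 macrophage markers Lgals3 (1.01 ± 0.20) and Ptprc (0.27 ± 0.07, under 0 with median centring, above background on 1 double null array) rose; the median was -0.04, the mean 0.04 and the test pointed up (camera adjusted p = 0.94). A single lymphocyte marker was measured, at -0.03, and the list was not tested. Of 5 erythrocyte markers none passed (median 0.35, camera adjusted p = 0.216). Of 9 adipocyte markers Retn alone rose (0.27 ± 0.09, adjusted p = 0.0485; under 0 with median centring, above background on 1 double null array), and none passed adjusted over the list alone (median 0.67, camera adjusted p = 0.0586).

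Of 10 skeletal muscle markers the fast genes Myh4 and Atp2a1 fell, as reported above, and Myh1, chosen after its value was seen, rose (2 fell and 7 rose adjusted over the list alone; median 0.80, mean 0.37, camera adjusted p = 0.216). Of 13 immediate early genes Ccn1 (0.73 ± 0.20; under 0 with median centring) and, chosen after its value was seen, Atf3 rose (median 0.25, camera adjusted p = 0.0779). Myc passed too, but its probe was well above background on no double null and 1 wild type array, so no rise is drawn from it. Of 14 unfolded protein response genes the chaperone Hspa5 (-0.69 ± 0.09), Hsp90b1 and Calr, the last 2 chosen after their values were seen, fell and Asns rose (0.96 ± 0.24; under 0 with median centring; list median -0.06, camera adjusted p = 0.285). Of 13 circadian genes Nr1d1 (-0.90 ± 0.22) and Hlf (-0.62 ± 0.21) fell (median -0.10, camera adjusted p = 0.328), and of 16 interferon genes Bst2 and Gbp2 (-0.59 ± 0.20) fell (median -0.10, camera adjusted p = 0.317). No gene passed among 7 cyclin-dependent kinase inhibitors and pocket proteins (median 0.09, camera adjusted p = 0.655).

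Of the 83 genes examined one by one that passed in this comparison, 61 passed without each array in turn. The other 22 included Cenpa, Myl4, Pdgfrb, Ptprc, Retn, Hlf, Bst2 and Gbp2, whose adjusted p was 0.107, 0.0663, 0.102, 0.0525, 0.138, 0.139, 0.101 and 0.118 at the highest. The remaining 14 were chosen after their values were seen, namely Xirp1, Myl7, Ndufb3, Rfc5, Prim1, Ldha and Bnip3l (0.0770, 0.123, 0.0889, 0.0931, 0.0941, 0.116 and 0.0676 at the highest) and Rgs5, Cnn1, Tagln, Myh1, Atf3, Hsp90b1 and Calr (0.0875, 0.114, 0.106, 0.0726, 0.0792, 0.0554 and 0.0786). With median centring Ldha, Gabarapl1, Bnip3l, Cnn1, Tagln, Myh1 and Atf3 were under 0. Of 840 genes that passed and had several probes, 121 had a probe of the opposite sign and 7 a probe that passed with the opposite sign.

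The labels do not give the sex of the mice. Of 3 measured sex-linked genes none passed (median 0.10, camera adjusted p = 0.809). Ddx3y was at 1.43, -0.20, 1.02 and 0.93 on double null 1, 2, 3 and 4, at 1.26, -0.59, 1.31 and 0.78 on the wild type arrays, at 0.42, -0.54, 1.04 and -0.30 on the MuRF1 null MuRF2 het arrays and at -0.34, -0.39, -0.54 and 1.35 on the MuRF1 het MuRF2 null arrays. Ddx3y was above background on 3 wild type, 3 double null, 2 MuRF1 null MuRF2 het and 1 MuRF1 het MuRF2 null array. By these counts Y-linked signal was balanced only between double null and wild type. In the other comparisons sex is not separated from genotype.

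The cell cycle inhibitor Cdkn1a, which did not pass in double null hearts, fell by 0.82 in MuRF1 het MuRF2 null against wild type hearts (adjusted p = 0.00949) and was chosen there after its value was seen.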
